A study of Mus musculus with 48 samples.

How the data were processed

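RNA of the striatum of 6-month-old C57BL/6 mice was measured by sequencing in 48 libraries, prepared with a stranded Illumina TruSeq protocol after RNeasy extraction. The deposited count table holds reads per gene as whole numbers, made by the authors with no scaling between libraries. A deposited FPKM table holds fragment counts scaled by gene length and library total, computed by the authors; in every library its values equal the counts divided by a fixed length per gene and by the library total, so it is the same data in another scaling. Per the submitters' processing notes the tools were STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 with the builds GRCm38 and mm10; the annotation release, the strand setting and the definition of gene length are not stated. Coordinates were taken from GENCODE M21 on GRCm38 by gene identifier and were found for 19893 of the 19975 genes tested. Each library was assigned to its group, sex and replicate number through the column name given in its label, and is named here by group, sex letter and number. The labels do not state that each library is a separate mouse, which is assumed. Library totals ran from 33.7 to 52.8 M counts, and the 28820 genes not tested held 0.0383% of the counts. No other columns with values per sample were in the files.

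Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group (a minimum count of 10, a minimum total of 15), TMM scaling (factors 0.956 to 1.09), glmQLFit with robust estimation on group means with sex as a covariate, and two-sided glmQLFTest contrasts over all 48 libraries. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, for each of 11 comparisons: 8 between groups, 2 interactions of Q140 with Msh3 genotype and 1 difference of the Q140 effect between the sexes. CPM were computed with the TMM-scaled library sizes. With 7 to 9 libraries a group, the count of reads limits precision only for weakly expressed genes; differences between mice limit the rest.

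Fixed before the data were examined were the groups, the comparisons and their tests, the alternatives, 27 gene lists and the rule for named genes. The lists cover MSN identity (shared, D1 and D2), activity-regulated genes, beta protocadherins, homeobox and other Polycomb-target factors, cholesterol synthesis, mismatch repair and repeat stability, p53 and DNA damage, heat shock, interferon response, mitochondrially encoded and nuclear-encoded respiratory genes, glutamate and GABA receptors, potassium channels, and markers of astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, cholinergic and GABAergic interneurons, cortical, septal, pallidal and thalamic neurons, choroid plexus and ependyma, blood and sex. Named genes are Msh3 and Htt; in each comparison the 6 largest rises and 6 largest falls past the threshold (4 and 4 outside Q140 against wild type and Q140 Msh3-/- against Q140) with an average log2 CPM of at least 0 and a symbol that is no clone name; and up to 4 called members of each list by smallest p, or up to 2 as values where none was called. A gene named in a comparison may be given in others. Some results for single genes are not reported here.

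Lists were tested with camera in limma 3.58.1 on voom values with its preset correlation of 0.01, adjusted over the 27 lists in a comparison, and again with a correlation estimated from each list's own members. Members called were counted over all genes tested and adjusted over the list alone. The share of the Q140 effect kept on an Msh3 background is the mean signed log2 change there over the mean in Msh3+/+ mice. Genes and signs were chosen in libraries of odd replicate numbers and measured in those of even numbers, then the reverse, and the results averaged. Intervals are 95% percentile intervals of 1000 bootstraps of libraries within group and sex. Wild type and Q140 libraries were also kept within odd or even numbers, and the chosen genes were held fixed. Wild type F2, the only even-numbered wild type female, entered every bootstrap, so the intervals may understate the spread between mice. Genes changed back were those called in both comparisons with opposite sign, set beside independent lists, 20 simulated data sets of unchanged groups, and a division of the Q140 libraries by replicate number. Positions near Msh3 and Htt were tested with Fisher's exact test in a window of 20 Mb, and with 10 and 5 Mb as alternatives.

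The pipeline was tested on simulated data with 200 changed genes of known size, and a planted shift of a list was ranked at the top of the lists. Alternatives were RLE scaling, DESeq2 1.42.0, no count filter, a stricter filter (1 CPM in 24 libraries), no sex covariate, only the groups compared, replicate number as a block, plate column or plate row of the well address as a covariate, limma-voom with the stem of the animal code as a random block, limma on log2 FPKM with offsets of 0.1 and 1 (at least 0.5 FPKM in 7 libraries) and with no filter, and each library left out in turn. After the data were seen, fits without the Q140 Msh3+/- library F1 and the Msh3+/- library F5 were added, and list tests without the library that stands apart in the list. Every comparison was also run on 25 splits of the libraries, the real one included. No library was left out of the reported values. Correlations and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.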

Results

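RNA from the striatum was sequenced in 48 libraries, taken here as 48 separate mice, 24 female and 24 male, all 6 months old and on a C57BL/6 background. Q140 is a heterozygous knock-in of an expanded CAG repeat into Htt, a mouse model of Huntington's disease, and Msh3 encodes a mismatch repair protein that acts on small loops in DNA. The libraries fell into 6 groups by label: wild type (n = 7), Q140 (n = 8), Msh3+/- (n = 9), Msh3-/- (n = 8), Q140 Msh3+/- (n = 8) and Q140 Msh3-/- (n = 8). Counts per library ran from 33.7 to 52.8 M with a median of 45 M, and 19975 of the 48795 genes in the table had enough reads to be tested. Biological variation between libraries of a group came to a coefficient of 10.3%. Group levels are given as mean CPM (counts scaled by library size) ± SD, changes as log2 fold changes, and "rose", "fell" or "changed" mark a gene past an adjusted p of 0.05. Rankings leave out weakly expressed genes and clone names.

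Msh3 reads were higher, not lower, in the libraries labelled as Msh3 mutants. The level of Msh3 was 31.0 ± 1.46 CPM in wild type (n = 7), 77.4 ± 4.74 in Msh3+/- (n = 9) and 119.7 ± 7.03 in Msh3-/- (n = 8), which is 2.5-fold and 3.86-fold of wild type. On the Q140 side it was 32.1 ± 1.27 CPM in Q140, 77.0 ± 3.14 in Q140 Msh3+/- and 125.2 ± 6.6 in Q140 Msh3-/- (n = 8 each). The ranges of the 3 Msh3 label classes did not overlap. The series design gives 7 to 8 animals a group while 9 libraries carry the Msh3+/- label. All 9 were at 68.2 to 85.4 CPM of Msh3. Counts per gene cannot show whether a transcript is functional, so the groups are named here by their labels, and directions along Msh3 genotype rest on those labels. Htt was at 209.2 ± 3.15 CPM in wild type and fell in Q140 to 191.7 ± 16.3 CPM (-0.13, SE 0.042, adjusted p = 0.0249). The Xist level was at least 1521 CPM in libraries labelled female and at most 1.43 CPM in those labelled male, and 0 of the 48 libraries went against their sex label.

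**Figure D1:**
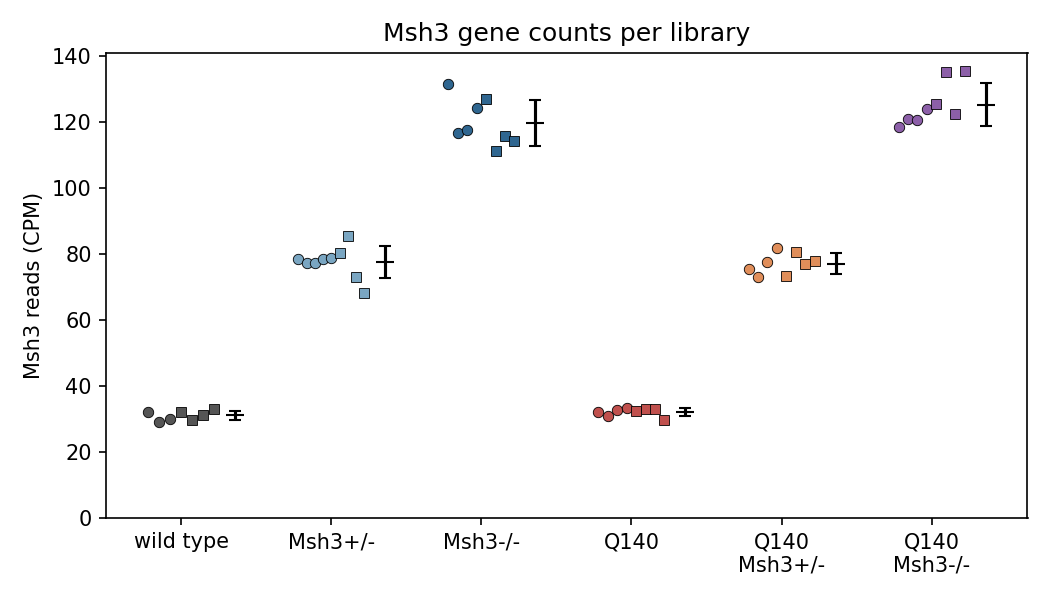
Msh3 level in each library, in CPM, by group; circles are female and squares male mice, and bars give the mean ± SD. Wild type and Q140 libraries sit near 31.0 and 32.1 CPM, and the libraries labelled Msh3-/- and Q140 Msh3-/- near 119.7 and 125.2 CPM.

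Q140 was compared with wild type to ask how the expanded repeat changes the striatal transcriptome at 6 months. Q140 changed 3969 genes, of which 1926 rose and 2043 fell, most by little: the median size was 0.23, 429 genes passed 1.5-fold and 140 passed 2-fold. Among named genes with an average log2 CPM of at least 0, the steepest falls were in Aoah (-2.06, SE 0.28), which encodes an enzyme that inactivates lipopolysaccharide, in the transcription factor Mafa (-2.0), in the Wnt ligand Wnt8b (-1.69), in Dgat2l6 (-1.68), in the glutathione peroxidase Gpx6 (-1.68) and in Ddit4l (-1.64), a relative of an inhibitor of mTOR signalling. Ddit4l went from 35.1 ± 3.83 CPM in wild type (n = 7) to 11.3 ± 3.93 in Q140 (n = 8). By the same limit the steepest rises were in the chemokine Ccl28 (1.27), the Polycomb-associated gene Sfmbt2 (1.27), cardiac troponin Tnnt2 (1.23), the desmoglein Dsg1c (1.20), titin, Ttn (1.16), and the cell-cycle arrest gene Rprm (1.13). Sfmbt2 went from 3.23 ± 0.447 CPM to 7.79 ± 2.52 CPM.

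Genes that mark medium spiny neurons (MSN), the main neurons of the striatum, fell almost throughout in Q140. Of 29 measured Pan-MSN genes, shared by both MSN classes, 28 fell and none rose (28 adjusted over the list alone; camera adjusted p = 3.37e-38, and adjusted p = 0.0205 with an estimated correlation). The sodium channel subunit Scn4b went from 1900 ± 85.2 CPM in wild type to 990.4 ± 215 in Q140, the adenylyl cyclase Adcy5 fell by 0.64, the phosphodiesterase Pde1b by 0.53 and the phosphoprotein Arpp21 by 0.63. Of 9 markers of indirect-pathway (D2) neurons, 6 fell (7 adjusted over the list alone; camera adjusted p = 1.24e-07, but adjusted p = 0.0544 with an estimated correlation). Among these, proenkephalin, Penk, went from 1952 ± 183 to 964.7 ± 142 CPM, the adenosine receptor Adora2a fell by 0.65, the dopamine receptor Drd2 by 0.56 and Gpr6 by 0.54. The 10 direct-pathway (D1) markers went both ways, with 3 rising and 2 falling (5 adjusted over the list alone; camera adjusted p = 0.35): the dopamine receptor Drd1 (-0.57) and the muscarinic receptor Chrm4 (-0.55) fell, and the transcription factor Isl1 (0.35) and the substance P precursor Tac1 (0.18) rose.

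**Figure D2:**
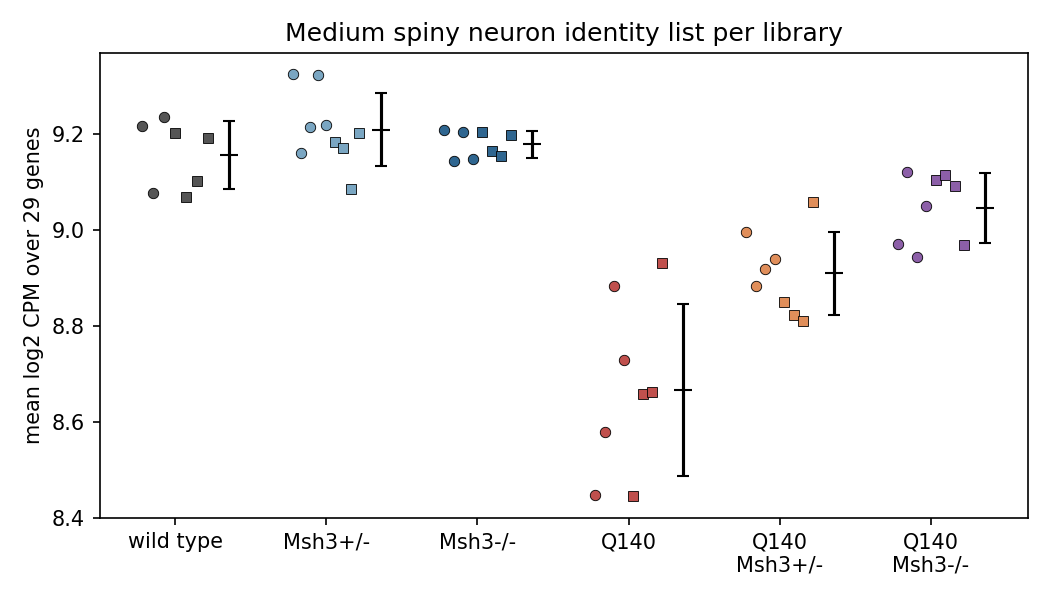
Mean log2 CPM of the 29 Pan-MSN genes in each library, by group; circles are female and squares male mice, and bars give the mean ± SD. The level was 9.16 in wild type, 8.67 in Q140, 8.91 in Q140 Msh3+/- and 9.05 in Q140 Msh3-/-.

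Receptors, channels and activity-dependent genes of neurons were also lower in Q140. The potassium channel list shares Kcnh4, Kcnab1 and Kcnj4 with the Pan-MSN list. Of 36 potassium channel subunits, 19 fell (23 adjusted over the list alone; camera adjusted p = 2.31e-09, but adjusted p = 0.0544 with an estimated correlation), among them Kcnh4 (-0.66), Kcnab1 (-0.46) and Kcnh3 (-0.42). Of 29 glutamate and GABA receptor subunits, 13 fell (14 adjusted over the list alone; camera adjusted p = 8.27e-07, but adjusted p = 0.0983 with an estimated correlation), including Grik2 (-0.44), Gabrd (-0.43) and Grm5 (-0.41). Of 21 activity-regulated early genes, 9 fell (10 adjusted over the list alone; camera adjusted p = 9.53e-06, but adjusted p = 0.357 with an estimated correlation), including the postsynaptic scaffold Homer1 (-0.79), the transcription factors Egr2 (-1.59) and Egr3 (-0.63), and Ier5 (-0.43). Without Q140 M2, the library lowest in this list, 8 fell (camera adjusted p = 0.000546). The beta protocadherins, a cluster of neuronal adhesion genes, went the other way: 12 of 22 rose and 1 fell (14 adjusted over the list alone; camera adjusted p = 1.22e-07, but adjusted p = 0.0983 with an estimated correlation). Pcdhb3 went from 4.32 ± 0.484 to 6.9 ± 0.63 CPM, Pcdhb9 rose by 0.51, Pcdhb22 by 0.43 and Pcdhb17 by 0.33.

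Among 21 homeobox and other Polycomb-target factors, 3 rose and 1 fell (4 adjusted over the list alone; camera adjusted p = 0.588): Wt1 (3.59), Six3 (0.22) and Dlx5 (0.19) rose and Dlx6 (-0.16) fell. Wt1, a developmental transcription factor, was at 0.0875 ± 0.0591 CPM in wild type and 1.09 ± 0.791 CPM in Q140. Of 20 mismatch repair and repeat-stability genes, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0166, but adjusted p = 0.0983 with an estimated correlation), namely Neil1 (0.21), Rrm2b (0.19), Apex1 (0.16) and Rpa1 (0.11). Neil1 and Apex1 act in base excision repair and Rrm2b in nucleotide supply, not in mismatch recognition. Of 20 p53 and DNA damage genes, 1 rose and 4 fell (7 adjusted over the list alone; camera adjusted p = 0.617), with Plk2 (-0.23), Zmat3 (-0.17) and Ddit4l falling and the apoptosis effector Bax (0.13) rising; the median of this list was 0.03 and its camera direction was down. Of 23 cholesterol synthesis genes, 4 rose and 4 fell (11 adjusted over the list alone; camera adjusted p = 0.588), with falls in Msmo1 (-0.26) and the regulator Srebf2 (-0.24) and a rise in Tm7sf2 (0.30). Of 32 nuclear-encoded oxidative phosphorylation genes, 7 rose (8 adjusted over the list alone; camera adjusted p = 0.0013, but adjusted p = 0.657 with an estimated correlation), such as Cyc1 (0.19), Cox6c (0.14) and Ndufv1 (0.13). Of 13 mitochondrially encoded genes, mt-Nd6 (-0.26) and mt-Nd2 (-0.20) fell (2 adjusted over the list alone; camera adjusted p = 0.236). Of 19 heat shock genes, only Hspa4 (-0.20) fell (1 adjusted over the list alone); the camera adjusted p of 0.0446 was lost with an estimated correlation (adjusted p = 0.737), and the list's median of -0.07 turned to 0.006 on FPKM. None of 22 interferon genes passed (0 adjusted over the list alone; camera adjusted p = 0.742), with a value of -0.25 for Ifih1. Without wild type F3, which stood apart in this list too, its median turned from -0.09 to 0.25.

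Astrocyte, microglia and vessel markers were lower in Q140 by less than the Pan-MSN genes, and by how much depends on scaling. From TMM scaling to scaling by library totals the median went from -0.13 to -0.05 for astrocyte, from -0.15 to -0.06 for microglia and from -0.16 to -0.08 for endothelial and mural markers. It went from -0.10 to -0.02 for oligodendrocyte and from -0.07 to 0.01 for precursor markers. For the Pan-MSN genes it went from -0.43 to -0.36. Of 16 astrocyte markers, 7 fell (7 adjusted over the list alone; camera adjusted p = 0.00118, but adjusted p = 0.126 with an estimated correlation), among them Ppp1r3c (-0.39), the glutamate transporter Slc1a2 (-0.32), the water channel Aqp4 (-0.23) and S1pr1 (-0.20). Of 16 endothelial and mural markers, Tek (-0.33), Rgs5 (-0.23), Pecam1 (-0.21) and Abcb1a (-0.20) fell (4 adjusted over the list alone; camera adjusted p = 0.00379, but adjusted p = 0.211 with an estimated correlation). Of 16 microglia markers, C1qa (-0.23), Csf1r (-0.21) and Siglech (-0.18) fell (6 adjusted over the list alone; camera adjusted p = 0.00118, but adjusted p = 0.517 with an estimated correlation). Without wild type F3, the library highest in this list, 1 microglia marker fell (0 adjusted over the list alone; camera adjusted p = 0.0233) and the median went from -0.15 to -0.09. Ugt8a (-0.27) fell among 16 oligodendrocyte markers (0 adjusted over the list alone), Pdgfra (-0.16) among 12 precursor markers (1 adjusted over the list alone), Nos1 (-0.25) and Th (-0.24) among 10 GABAergic interneuron markers (2 adjusted over the list alone) and Tacr1 (-0.18) among 8 cholinergic interneuron markers (2 adjusted over the list alone). Among 14 cortical markers, Cux2 (0.37) rose and Rasgrf2 (-0.45) fell (2 adjusted over the list alone), Six3 rose among 12 septal, pallidal and thalamic markers (1 adjusted over the list alone), and Kcnj13 (-3.70) fell among 15 choroid plexus and ependymal markers (0 adjusted over the list alone). Camera called none of these 7 lists. The choroid plexus transcript Ttr stood at 119.5 ± 210 CPM in wild type and 13.8 ± 11.6 in Q140. Within wild type, M2 was highest in this list, at a mean log2 CPM of 2.84 against at most 1.07 in the others. Without Q140 Msh3+/- F1 and Msh3+/- F5, a fit chosen after seeing the data, 7 of the 15 markers fell. None of 5 blood genes passed (0 adjusted over the list alone), with -1.78 for Hbb-bt and -1.05 for Alas2. Of 10 sex-linked genes only Tsix (0.93) rose (1 adjusted over the list alone); Tsix lies antisense to Xist, and the strand setting of the counting is not stated.

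**Figure D3:**
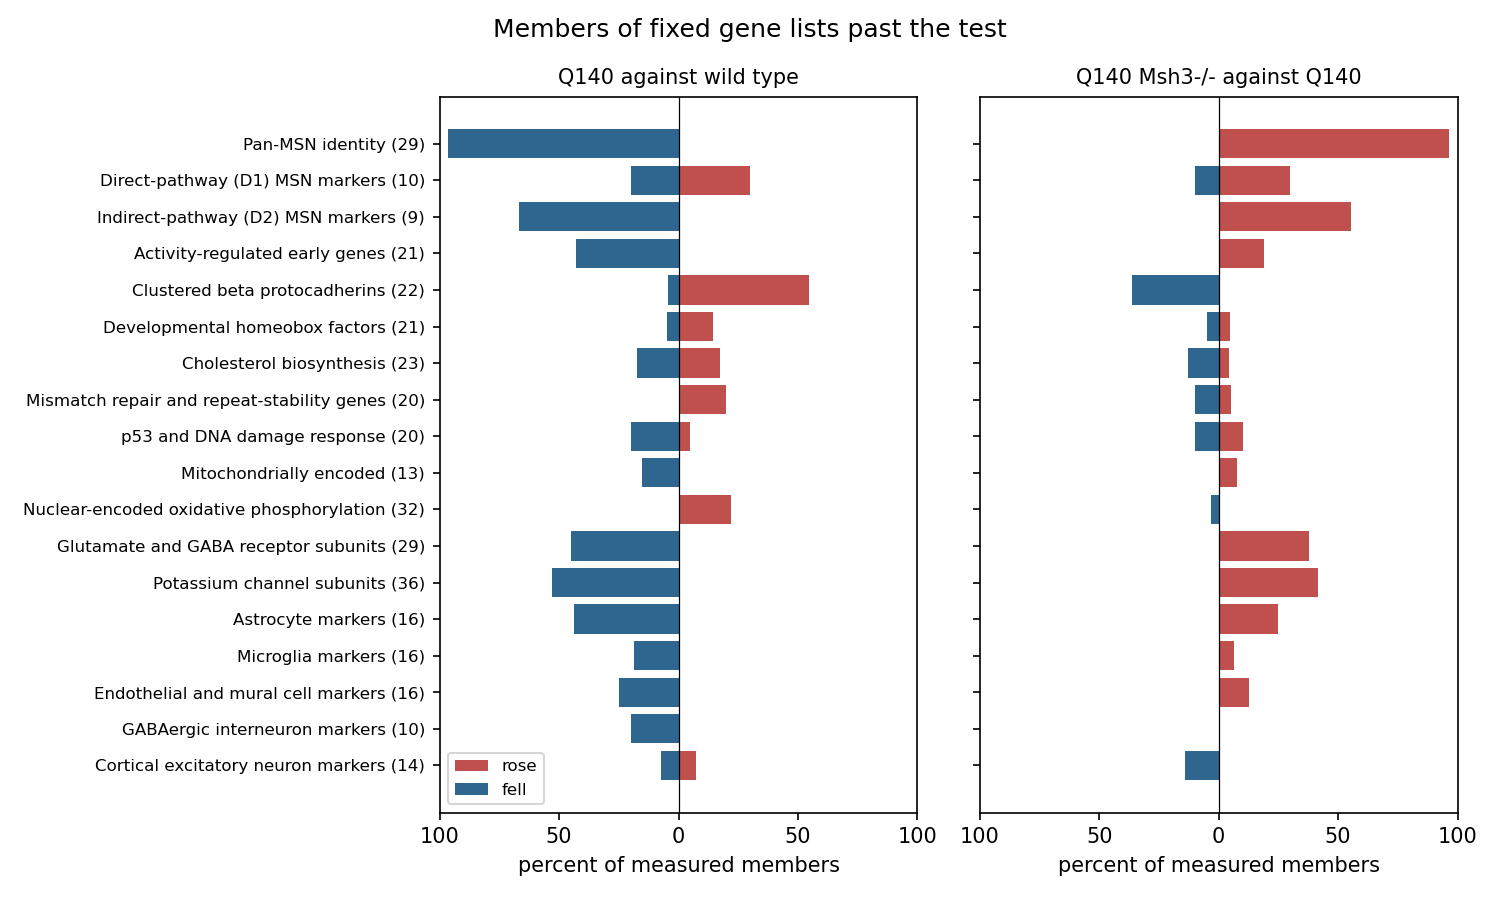
Percent of the measured members of gene lists fixed in advance that rose or fell, in Q140 against wild type and in Q140 Msh3-/- against Q140. Lists are shown where more than a single member was called in Q140 against wild type. Of the 29 Pan-MSN genes, 28 fell in Q140 against wild type and 28 were higher in Q140 Msh3-/- than in Q140.

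The 3969 calls came from edgeR, where 6365 genes had an unadjusted p under 0.05 and chance alone would give 999. The balance of directions depends on scaling: with libraries scaled by their totals, in FPKM, limma called 6030 genes, 4944 higher and 1086 lower, and the median of all genes moved from 0.0145 to 0.0881. With estimated correlations, the Pan-MSN call alone held among the lists. In simulated data with known changes, the comparison recovered 82% of genes changed 1.3-fold and 98% at 2-fold, and 7 of 157 calls were false.

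Without Q140, the Msh3 genotypes barely changed the striatum beyond Msh3 itself and its chromosomal neighbours. In Msh3+/- against wild type, 2 genes rose and none fell: Msh3 (1.32) and F2r (0.57), which encodes the thrombin receptor. In Msh3-/- against wild type 6 genes changed: Msh3 (1.95) and F2r (1.06) rose, and the Ras exchange factor Rasgrf2 (-1.43), AW495222 (-1.14), the muscle-related gene Cmya5 (-0.90) and the synaptic vesicle gene Sv2c (-0.28) fell. F2r went from 4.01 ± 0.582 CPM in wild type to 5.95 ± 0.849 in Msh3+/- and 8.38 ± 1.38 in Msh3-/-, and Rasgrf2 from 58.4 ± 23.3 to 35.3 ± 4.71 and 21.4 ± 3.43 CPM. On GRCm38 chromosome 13, Msh3 (ENSMUSG00000014850) spans 92211872 to 92355003, and the 5 others lie within 3.6 Mb of it: Rasgrf2 at 91880400 to 92131656, Cmya5 at 93040713 to 93144724, AW495222 at 93706182 to 93719175, F2r at 95601803 to 95618487 and Sv2c at 95954594 to 96132577. All 5 lay within 20 Mb of Msh3, against 1.09% of the genes tested (Fisher exact p = 1.44e-10, two-sided).

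**Figure D4:**
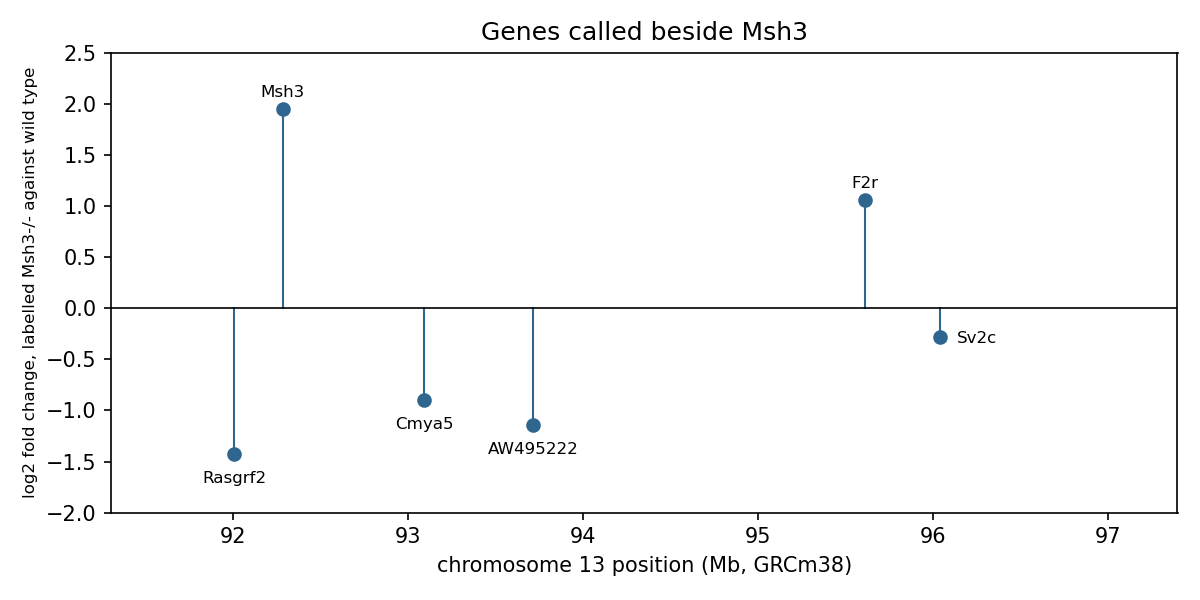
Region of GRCm38 chromosome 13 around Msh3, with the genes called in Msh3-/- against wild type and their log2 fold changes. Sv2c, 3.6 Mb away, is the farthest, and Rasgrf2 (-1.43) and AW495222 (-1.14) have the largest changes among the neighbours.

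No Pan-MSN gene passed in either Msh3 genotype: 0 of 29 in each (0 adjusted over the list alone in each), with levels of 9.21 ± 0.08 log2 CPM in Msh3+/- and 9.18 ± 0.03 in Msh3-/- against 9.16 ± 0.07 in wild type. Of the 27 lists, members passed only in the mismatch repair list, through Msh3 itself (1 adjusted over the list alone in each genotype), and in the cortical list, through Rasgrf2 in Msh3-/- (1 adjusted over the list alone). In Msh3+/-, camera called oligodendrocyte markers lower (adjusted p = 2.29e-05) and microglia markers lower (adjusted p = 2.49e-05) with 0 members called, and with an estimated correlation these became adjusted p = 0.618 and adjusted p = 0.452. The microglia call was also lost without wild type F3 (adjusted p = 0.0604), and so was a camera call of interferon genes with 0 members called. At an unadjusted p under 0.05 there were 943 genes in Msh3+/- and 807 in Msh3-/-, where chance gives 999. The Msh3+/- count went from 2 to 1 on leaving out Msh3+/- F4 or M3 or wild type F1, M1 or M4. It was also 1 with only the groups compared or with a plate covariate. Without wild type F3 it stayed at 2, but 1 of the 2 calls was lost and another gene was called lower. Msh3+/- F5 stood apart in cortical markers, and leaving it out together with Q140 Msh3+/- F1 left 2 genes.

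Q140 Msh3-/- was compared with Q140 to ask what the Msh3-/- genotype changes in mice that carry the expanded repeat. It changed 2374 genes, 1368 higher and 1006 lower, with a median size of 0.21; 180 passed 1.5-fold and 43 passed 2-fold. Among named genes with an average log2 CPM of at least 0, those that fell in Q140 led the rises after Msh3: Aoah (1.46, SE 0.28), Mafa (1.38), Gpx6 (1.18), the serine protease Tmprss6 (1.13), Wnt8b (1.11) and Ddit4l (1.1). Ddit4l stood at 11.3 ± 3.93 CPM in Q140 and 24.2 ± 4.34 in Q140 Msh3-/- (n = 8 each). By the same limit the steepest falls were in AW495222 (-2.02), Sfmbt2 (-1.25), Rasgrf2 (-0.96), Rprm (-0.85), Tsix (-0.81) and the Polycomb gene Cbx8 (-0.80), of which AW495222 and Rasgrf2 are neighbours of Msh3 that also fell without Q140. Sfmbt2 went from 7.79 ± 2.52 to 3.28 ± 0.46 CPM.

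MSN genes were higher in Q140 Msh3-/- than in Q140. All but 1 of the 29 Pan-MSN genes rose and none fell (28 adjusted over the list alone; camera adjusted p = 4.88e-40, and adjusted p = 0.0158 with an estimated correlation). Scn4b went from 990.4 ± 215 to 1536 ± 160 CPM, the phosphodiesterase Pde10a rose by 0.56, Arpp21 by 0.52 and Adcy5 by 0.41. Of 9 D2 markers 5 rose (5 adjusted over the list alone; camera adjusted p = 3.05e-07, but adjusted p = 0.0546 with an estimated correlation), with Penk going from 964.7 ± 142 to 1486 ± 124 CPM and Adora2a (0.41), Drd2 (0.39) and Gpr6 (0.38) also higher. Of 10 D1 markers 3 rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.0148, but adjusted p = 0.111 with an estimated correlation): Drd1 (0.43), Chrm4 (0.35) and Slc35d3 (0.21) rose and Isl1 (-0.20) fell. Of 36 potassium channel subunits 15 rose (18 adjusted over the list alone; camera adjusted p = 1.43e-10, and adjusted p = 0.0491 with an estimated correlation), such as Kcnh4 (0.52), Kcnab1 (0.34) and Kcnq5 (0.29). Of 29 receptor subunits 11 rose (13 adjusted over the list alone; camera adjusted p = 1.52e-06, but adjusted p = 0.111 with an estimated correlation), including Gabrd (0.34), Grik2 (0.34) and Grm5 (0.31). Homer1 (0.61), Nptx2 (0.63), Egr3 (0.45) and Ier5 (0.32) rose among 21 activity-regulated genes (4 adjusted over the list alone; camera adjusted p = 0.0588).

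Beta protocadherins were lower: 8 of 22 fell (13 adjusted over the list alone; camera adjusted p = 1.48e-08, but adjusted p = 0.0815 with an estimated correlation), among them Pcdhb3 (-0.57), Pcdhb7 (-0.38), Pcdhb9 (-0.35) and Pcdhb17 (-0.24). Wt1 (-3.90) fell to 0.0693 ± 0.0642 CPM. Of 16 astrocyte markers Slc1a2 (0.22), Ppp1r3c (0.21), S1pr1 (0.14) and Slc1a3 (0.11) rose (5 adjusted over the list alone; camera adjusted p = 0.00508, but adjusted p = 0.201 with an estimated correlation). Vwf (0.39) and Rgs5 (0.20) rose among 16 endothelial and mural markers (2 adjusted over the list alone; camera adjusted p = 0.0225, but adjusted p = 0.38 with an estimated correlation). Among 32 oxidative phosphorylation genes Cyc1 (-0.13) fell (1 adjusted over the list alone; camera adjusted p = 0.0225, but adjusted p = 0.888 with an estimated correlation). In the mismatch repair list Msh3 (1.96) rose and Rrm2b (-0.12) and Neil1 (-0.20) fell (3 adjusted over the list alone), and in the p53 list Ddit4l and Plk2 (0.22) rose and Sesn2 (-0.27) and Phlda3 (-0.29) fell (5 adjusted over the list alone). Htt rose by 0.17 (adjusted p = 0.00317), from 191.7 ± 16.3 to 215.4 ± 12.1 CPM. At an unadjusted p under 0.05 there were 4977 genes. Scaled by library totals in FPKM, limma called 4280 genes, 819 higher and 3461 lower.

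Q140 Msh3+/- against Q140 gave a smaller change of the same kind, beside a set of choroid plexus genes from a single library. It changed 395 genes, 256 higher and 139 lower. Of the 29 Pan-MSN genes 14 rose (28 adjusted over the list alone; camera adjusted p = 1.87e-31, but adjusted p = 0.0541 with an estimated correlation), with Scn4b going from 990.4 ± 215 to 1317 ± 134 CPM and Pde10a (0.37), Arpp21 (0.31) and Adcy5 (0.29) also higher. Penk rose from 964.7 ± 142 to 1266 ± 189 CPM as the 1 gene of 9 D2 markers that passed (6 adjusted over the list alone; camera adjusted p = 2.23e-06, but adjusted p = 0.124 with an estimated correlation). Drd1 (0.24) and Chrm4 (0.23) rose among 10 D1 markers (2 adjusted over the list alone; camera adjusted p = 0.0226, but adjusted p = 0.18 with an estimated correlation). Grik2 (0.31), Grm5 (0.24) and Gabrd (0.21) were among 6 of 29 receptor subunits that rose (10 adjusted over the list alone; camera adjusted p = 2.23e-06, but adjusted p = 0.176 with an estimated correlation). Kcnab1 (0.22), Kcnq3 (0.22) and Kcna4 (0.21) were among 6 of 36 potassium channel subunits that rose (13 adjusted over the list alone; camera adjusted p = 2.4e-06, but adjusted p = 0.176 with an estimated correlation). Pcdhb9 (-0.23) was the 1 of 22 beta protocadherins that fell (4 adjusted over the list alone; camera adjusted p = 2.98e-05, but adjusted p = 0.254 with an estimated correlation). Oligodendrocyte markers had 0 of 16 members called (0 adjusted over the list alone; camera adjusted p = 2.98e-05, but adjusted p = 0.574 with an estimated correlation), with Mag at -0.23. Among named genes with an average log2 CPM of at least 0, the steepest falls were in the potassium channel gene Kcng4 (-1.17), Sfmbt2 (-0.95), AW495222 (-0.84) and Zbtb7c (-0.63), and the weakly expressed Wt1 (-3.95) fell to 0.0675 ± 0.0481 CPM.

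By the same limit the largest rises in that comparison were choroid plexus genes: Ttr (5.22), Mfrp (4.27), Slc4a5 (4.06) and Tmem72 (3.61), and 8 of 15 choroid plexus and ependymal markers rose (10 adjusted over the list alone; camera adjusted p = 0.0213, but adjusted p = 0.609 with an estimated correlation). These came from the library Q140 Msh3+/- F1, and Ttr in this group was at 507.4 ± 1390 CPM. Leaving out this library and Msh3+/- F5, as an alternative chosen after seeing the data, left 116 genes, 73 higher and 43 lower, with 8 of the 29 Pan-MSN genes, 3 of 29 receptor subunits, 1 of 36 potassium channel subunits and 0 of 15 choroid plexus and ependymal markers rising, and Ttr stood at 0.14, Mfrp at -0.17, Slc4a5 at -0.40 and Tmem72 at -0.09. The calls of Kcng4, Zbtb7c, Pcdhb9, Chrm4, Gabrd, Kcnab1 and Kcnq3 were lost with them. The count of 395 moved with single libraries: without Q140 F1, F2, F3, F4, M1 or M4 it was 73, 113, 691, 259, 91 or 992, and without Q140 Msh3+/- F1, F4, M1 or M4 it was 123, 755, 256 or 104. It was 649 in DESeq2, 211 without a count filter, 125 with plate column as a covariate and 4 with only the groups compared, and FPKM scaled by library totals gave 795 genes, 237 higher and 558 lower.

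Between the Q140 Msh3 genotypes themselves few genes separated. Q140 Msh3-/- differed from Q140 Msh3+/- in 3 genes: Msh3 (0.70) was higher, and its neighbours AW495222 (-1.18) and Cmya5 (-0.51) were lower. None of 29 Pan-MSN genes passed (10 adjusted over the list alone), with values of 0.21 for Arpp21 and 0.19 for Ppp1r1b; camera placed the list higher (adjusted p = 6.93e-19, but adjusted p = 0.198 with an estimated correlation). Potassium channel subunits were placed higher (1 of 36 adjusted over the list alone; adjusted p = 4.08e-07, but adjusted p = 0.198 with an estimated correlation) and beta protocadherins lower (1 of 22 adjusted over the list alone; adjusted p = 6.06e-06, but adjusted p = 0.326 with an estimated correlation), with 0 members past the threshold over all genes. At an unadjusted p under 0.05 there were 1173 genes. Without Q140 Msh3-/- F3 the count was 6, and DESeq2 called 25.

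The effect of Q140 was then measured within each Msh3 genotype. Q140 Msh3+/- against Msh3+/- changed 1289 genes, 592 higher and 697 lower, and 1040 of these had also changed in the same direction in Q140 against wild type, which has no library in common. Among named genes with an average log2 CPM of at least 0, Wnt8b (-1.56), Mafa (-1.15), Aoah (-1.06) and the endopeptidase Phex (-1.0) fell most. Of 29 Pan-MSN genes 23 fell (28 adjusted over the list alone; camera adjusted p = 1.08e-35, and adjusted p = 0.0292 with an estimated correlation), with Scn4b at -0.56, Ppp1r1b, which encodes DARPP-32, and Arpp21 at -0.41, and Pde1b at -0.34. Penk (-0.63), Adora2a (-0.43), Gpr6 (-0.42) and Drd2 (-0.36) fell among 9 D2 markers (5 adjusted over the list alone; camera adjusted p = 5.13e-06, but adjusted p = 0.112 with an estimated correlation). Among D1 markers Drd1 (-0.39) and Chrm4 (-0.28) fell and Isl1 (0.26) rose (5 adjusted over the list alone). Of 36 potassium channel subunits 10 fell (13 adjusted over the list alone; camera adjusted p = 7.78e-09, but adjusted p = 0.101 with an estimated correlation), and of 29 receptor subunits 8 fell (11 adjusted over the list alone; camera adjusted p = 5.13e-06, but adjusted p = 0.196 with an estimated correlation). Of 22 beta protocadherins 6 rose and 1 fell (7 adjusted over the list alone; camera adjusted p = 0.000946, but adjusted p = 0.514 with an estimated correlation).

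By the same limit choroid plexus genes again led the rises on this background, with Ttr (4.74), Slc4a5 (4.16), Mfrp (4.11) and Tmem72 (3.72), and 9 of 15 choroid plexus and ependymal markers rose (11 adjusted over the list alone; camera adjusted p = 0.00166, but adjusted p = 0.551 with an estimated correlation). Without Q140 Msh3+/- F1 and Msh3+/- F5 these 4 genes stood at -0.58, -0.58, -0.53 and -0.06, and 1037 genes were called. With plate row as a covariate the count was 553, and FPKM scaled by library totals gave 2188 genes, 1769 higher and 419 lower. At an unadjusted p under 0.05 there were 3781 genes.

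On the Msh3-/- background Q140 changed 15 genes, 10 higher and 5 lower, and all 15 had changed in the same direction in Q140 against wild type. The rises included Tmc3 (0.67), the villin-like gene Vill (0.48), the serotonin receptor Htr2c (0.40) and the potassium channel gene Kcng1 (0.36), and the falls included Ddit4l (-0.61), Penk (-0.42), Ankrd35 (-0.38) and Pde1b (-0.22). Penk stood at 1983 ± 136 CPM in Msh3-/- and 1486 ± 124 in Q140 Msh3-/- (n = 8 each). Pde1b was the 1 of 29 Pan-MSN genes to pass (9 adjusted over the list alone; camera adjusted p = 1.29e-16, but adjusted p = 0.194 with an estimated correlation), and Penk the 1 of 9 D2 markers (5 adjusted over the list alone; camera adjusted p = 4.09e-06, but adjusted p = 0.151 with an estimated correlation). None of 22 beta protocadherins passed (7 adjusted over the list alone; camera adjusted p = 5.16e-06, but adjusted p = 0.2 with an estimated correlation), with 0.28 for Pcdhb19 and 0.22 for Pcdhb9. Oligodendrocyte markers were placed lower with 0 of 16 called (4 adjusted over the list alone; camera adjusted p = 1.73e-09, but adjusted p = 0.2 with an estimated correlation). At an unadjusted p under 0.05 there were 1342 genes. The count of 15 was 9 or 7 without Q140 Msh3-/- F1 or F3 and 8, 5 or 7 without Msh3-/- F2, M2 or M4; it was 29 in DESeq2, 9 without a count filter, 9 without the sex covariate, 23 with only the groups compared, and 8 or 2 with plate column or plate row as a covariate.

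Whether the Q140 effect differed between Msh3 genotypes was tested with an interaction term. On Msh3-/- against Msh3+/+ the effect differed in 478 genes, 334 with a positive and 144 with a negative term, and 476 of them had changed in Q140 against wild type with the opposite sign. This is in part built in, since the term contains that comparison with its sign turned and uses the same libraries. Among named genes with an average log2 CPM of at least 0, Mafa (1.83), Aoah (1.53), Dgat2l6 (1.44) and Wnt8b (1.31) had the largest positive terms, and Sfmbt2 (-1.16), Fam196b (-0.90), AW495222 (-0.88) and Cbx8 (-0.71) the largest negative ones. Of 29 Pan-MSN genes 16 had a positive term (28 adjusted over the list alone; camera adjusted p = 9.21e-32, but adjusted p = 0.0519 with an estimated correlation), with Scn4b at 0.67 (SE 0.11), Rgs4 at 0.58, Adcy5 at 0.45 and Arpp21 at 0.44. Penk (0.61), Gpr6 (0.38) and Drd2 (0.37) passed among 9 D2 markers (5 adjusted over the list alone; camera adjusted p = 2e-05, but adjusted p = 0.148 with an estimated correlation), and Drd1 (0.44), Chrm4 (0.42) and Isl1 (-0.29) among 10 D1 markers (3 adjusted over the list alone). Of 36 potassium channel subunits 8 had a positive term (13 adjusted over the list alone; camera adjusted p = 1.63e-08, but adjusted p = 0.117 with an estimated correlation), as had 6 of 29 receptor subunits (9 adjusted over the list alone; camera adjusted p = 3.17e-05, but adjusted p = 0.275 with an estimated correlation). Homer1 (0.67) and Egr3 (0.51) passed among activity-regulated genes (4 adjusted over the list alone; camera adjusted p = 0.00311, but adjusted p = 0.601 with an estimated correlation and 0.0811 without Q140 M2), and Pcdhb3 (-0.51) and Pcdhb22 (-0.26) among beta protocadherins (3 adjusted over the list alone; camera adjusted p = 0.000409, but adjusted p = 0.314 with an estimated correlation). The count of 478 was 262, 276 or 935 without Q140 F1, M1 or M4, 286 without Q140 Msh3-/- F2 and 302 without wild type M4, and it was 763 in DESeq2, 280 without a count filter and 64 with plate row as a covariate. FPKM scaled by library totals gave 1145 genes, 262 positive and 883 negative.

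On Msh3+/- the interaction passed in 0 genes by edgeR, with 1621 at an unadjusted p under 0.05 and 19 called by DESeq2; without Q140 M4 it passed in 24, and on FPKM limma called 1. Ddit4l stood at 0.86 (adjusted p = 0.113), Penk at 0.39, Scn4b at 0.39 and Adcy5 at 0.28. None of 29 Pan-MSN genes passed (9 adjusted over the list alone), and camera placed the list higher (adjusted p = 4.22e-16, but adjusted p = 0.27 with an estimated correlation). Choroid plexus markers had 0 of 15 passing (9 adjusted over the list alone; camera adjusted p = 0.000873, but adjusted p = 0.525 with an estimated correlation), with Ttr at 7.82. The libraries highest in these markers were Q140 Msh3+/- F1, at a mean log2 CPM of 4.73, and wild type M2, at 2.84. Without the former the list's median term went from 3.26 to 0.68 (camera adjusted p = 0.0247).

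The size of the Q140 effect kept on each background was estimated as a share, over genes chosen in a part of the wild type and Q140 libraries and measured in the rest. On the Msh3-/- background 34.1% of the effect was kept (95% interval 23.6 to 46.4) and on the Msh3+/- background 71.2% (55.7 to 88.7), a difference of 37.1 percentage points (20.7 to 55.7; 1000 bootstraps of libraries). The mean effect was 0.33 in Msh3+/+ mice, 0.24 on Msh3+/- and 0.11 on Msh3-/-, with 1267 and 531 genes chosen in the parts. Genes lower in Q140 kept 30.9% on Msh3-/- (19.1 to 43.8) and 68.1% on Msh3+/- (50.5 to 88.2); those higher in Q140 kept 40.6% (30.7 to 52.1) and 78.4% (64.5 to 93.9). Over the Pan-MSN list alone the shares were 27.0% and 59.9%. In simulated data with 50% and 100% kept, the estimates were 50.6% (48.2 to 53.4) and 99.4% (96.4 to 102.2). Simulated genes varied independently of each other, so this checks the bias of the estimate and not the width of the real intervals.

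**Figure D5:**
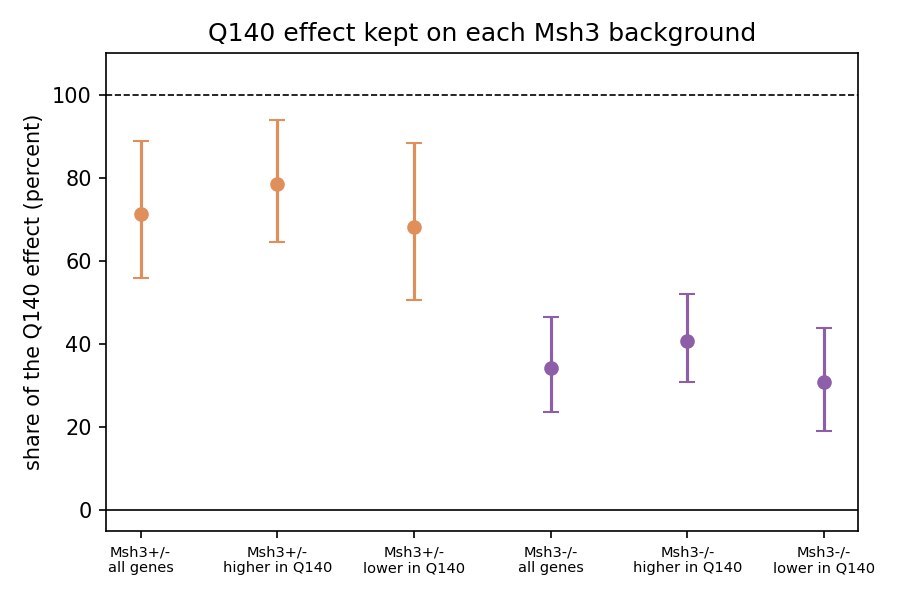
Share of the Q140 effect kept on the Msh3+/- and Msh3-/- backgrounds, in percent, with 95% bootstrap intervals. The Msh3-/- share is 34.1% and the Msh3+/- share 71.2%.

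Genes changed by Q140 and changed back in Q140 Msh3-/- numbered 1923, of which 768 rose and then fell, Sfmbt2 and Cbx8 among them, and 1155 fell and then rose, such as Penk and Drd1. That is 48.5% of the 3969 Q140 genes and 81% of the 2374, and 2 genes changed further in the Q140 direction. Both comparisons use the same Q140 libraries, which by itself gives such overlap. Independent lists of these sizes would share 237 genes with opposite sign. In 20 simulations of unchanged groups 0 genes were called in both comparisons with opposite sign. Top-ranked lists of these sizes in those simulations shared 860 such genes on average (at most 891). With the Q140 libraries divided between the comparisons by replicate number, so that none was shared, 514 and 968 genes changed back. In Q140 Msh3+/-, 342 genes changed back, 118 that rose and then fell and 224 that fell and then rose, which is 8.62% of the Q140 genes and 86.6% of the 395. There the independent overlap was 39.6, simulated top-ranked lists shared 203 (at most 222), and the divided libraries gave 4 and 278.

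Females and males were compared in their response to Q140. No gene differed between the sexes in its Q140 effect by edgeR, 1478 had an unadjusted p under 0.05, and DESeq2 also called 0; with only the groups compared edgeR called 1. Penk (-0.08), Scn4b (0.02) and Drd1 (0.01) had sex differences near 0, with adjusted p of 0.938, 0.988 and 0.984, in groups of 3 and 4 wild type and 4 and 4 Q140 mice.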

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

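Chosen only after the result was seen were the tests of the Msh3 label classes those of cell composition and scaling, and those of genes near Htt by Gm2420 reads; the tests of chance, of the neighbours of Msh3 and Htt, of single libraries, of the interaction and of the shares kept were planned.

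The interaction of Q140 with Msh3-/- passed in 478 genes, so the Q140 effect differed between Msh3 genotypes by a test of the difference itself. The shares of the Q140 effect kept on Msh3+/- and Msh3-/- differed by 37.1 percentage points (95% interval 20.7 to 55.7). Other splits of the same libraries, 25 per comparison with the real one included, were fitted in the same way. With 25 splits a comparison and no adjustment over the 11 comparisons, the splits can argue against chance but cannot exclude it. They argue against it, with only the real split (1 of 25) giving as many genes, for Q140 against wild type (3969, highest other 1549), Msh3-/- against wild type (6, highest other 0), Q140 Msh3+/- against Q140 (395, highest other 182), Q140 Msh3-/- against Q140 (2374, highest other 1), Q140 Msh3+/- against Msh3+/- (1289, highest other 2), Q140 Msh3-/- against Msh3-/- (15, highest other 1) and the interaction with Msh3-/- (478, highest other 0). For Q140 Msh3+/- against Q140 this holds for the main fit alone: the count was 116 without Q140 Msh3+/- F1 and Msh3+/- F5, 73 without Q140 F1, 125 with plate column as a covariate and 4 with only the groups compared, all below 182, and the splits were not run again under these settings. The splits do not argue against chance for the count of genes in Msh3+/- against wild type (2 genes, as many in 4 of 25 splits, highest other 200) and in Q140 Msh3-/- against Q140 Msh3+/- (3 genes, as many in 2 of 25, highest other 3). For Msh3 itself chance is argued against by its ranges, which did not overlap in either (68.2 to 85.4 CPM against 29.1 to 33, and 118 to 135 against 73 to 81.8). For the interaction with Msh3+/- (0 by edgeR, with 1621 at an unadjusted p under 0.05 and 19 by DESeq2; highest other 5) and the sex difference (0 by edgeR and DESeq2, with 1478 at an unadjusted p under 0.05; highest other 202) the splits decide nothing, since any split (25 of 25) gives at least 0 genes. Splits with 200 and 202 genes point to a structure among the libraries other than their groups, which was not traced.

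Genes beside the engineered genes were the first pattern weighed. All 5 genes other than Msh3 that changed in Msh3-/- against wild type lie within 20 Mb of Msh3 (Fisher exact p = 1.44e-10), which is consistent with DNA of another strain carried along with the engineered allele; an effect of the engineered allele on its neighbours was not tested and stays open for them. The same test was run on Q140 Msh3-/- against Q140, for which it was not planned. Of its called genes other than Msh3, 1.4% lay within 20 Mb of Msh3 against 1.09% of the genes tested (Fisher exact p = 0.138). Within 10 Mb the shares were 0.93% and 0.583% (Fisher exact p = 0.0293). Within 5 Mb they were 0.719%, or 17 genes, and 0.297% (Fisher exact p = 0.000363). Whether linked DNA accounts for these genes was not tested. Around Htt the tables argue against DNA of another strain as the source of the Q140 set. Of its genes 1.79% lie within 20 Mb of Htt, against 1.80% of the genes tested. Within 5 Mb of Htt the called genes were more frequent (1.11% against 0.764%). These 44 genes kept 29.7% of their Q140 change on the Msh3-/- background (21.6 to 38.8), beside 23.0% (14.6 to 32.4) for called genes beyond 20 Mb. In the 5 Q140 Msh3-/- libraries with reads of Gm2420, a gene 2.03 Mb from Htt that was above 0.136 CPM only in libraries with Q140, they kept 37.7% (26 to 50.6), beside 18.2% (8.09 to 29) beyond 20 Mb, and the median gene 20.8% beside 17.1%. In the 3 without such reads the order was the reverse, 16.1% (8.48 to 22.8) beside 31.1% (20.7 to 42.1). The median gene there kept 22.8% beside 29.8%. These 3 are all female (F1, F3 and F4), while the 5 with such reads are F2 and the males. A difference between the 5 and the 3 therefore cannot be told apart from a difference between the sexes. All these shares come from genes chosen and measured in the same wild type and Q140 libraries, which lowers them. Over the Q140 genes as a whole, that way gave 23.9% on Msh3-/- in place of 34.1%. Linked DNA would have kept the change in full but for this bias, so it is argued against as the source for all 44 genes, while for some of them it stays open. Abhd1, Dpysl5 and Atraid, picked for following Gm2420 among the Q140 Msh3 mutant libraries, are consistent with linked DNA: for 3 of 3 the Q140 group, not used to pick them, stood with the libraries that have Gm2420 reads, and the libraries without Q140 with those that lack them.

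Higher Msh3 reads in the labelled mutants were the second pattern. A single mislabelled library is argued against, since 0 of the 48 libraries had an Msh3 level inside the range of another label class. The 9 libraries labelled Msh3+/-, where the design gives 7 to 8 a group, also lay apart from Q140 Msh3+/- in the score of the Q140 genes, at -1.12 to -0.998 against -0.967 to -0.851, and none went against its sex label. An exchange of the Msh3 classes as a whole cannot be told apart from the labels as given, because the Msh3 read counts, 3.86-fold of wild type in Msh3-/-, the called neighbours of Msh3 and the shares of the Q140 effect kept would follow the classes under either naming. Transcription from or through the engineered allele was not tested, since the counts are per gene and show no exons. No biological explanation was tested.

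Lower Pan-MSN genes in Q140 were the third pattern. A lower share of MSN in the tissue would raise the markers of other cell types, but among astrocytes, oligodendrocytes, their precursors, microglia and endothelial cells the highest median was -0.07 (-0.0693, precursors), which turned to 0.0117 with libraries scaled by their totals, far from the size of the Pan-MSN change. Within the D1 list, Isl1 (0.35) and Tac1 (0.18) rose while Drd1 and Chrm4 fell. The mean log2 CPM of this list was 6.09 in wild type and 6.02 in Q140. Since its members went both ways, it does not decide between a loss of cells and a change within them. Scaling as the source is argued against, since the Pan-MSN median stayed at -0.36 (-0.357) with total scaling, against -0.43 with TMM. A change of expression within MSN in Q140 may account for the pattern, as a hypothesis found and tested on the same data.

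Among 192 sets of values, a measure in a group of libraries, 15 had a library standing apart by its gap to the nearest other; chance gives about 1 in 20, or 9.6. Htt was lowest in Q140 Msh3+/- F4 at 177.2 CPM. All other values are mean log2 CPM of a list. Activity-regulated genes were lowest in Q140 M2 at 3.515. Mismatch repair genes were lowest in Q140 Msh3+/- F2 at 3.627. The p53 list was highest in Q140 Msh3+/- F1 at 3.938. Heat shock genes were highest in Msh3+/- F1 at 6.184 and lowest in Q140 Msh3-/- M2 at 5.647. Interferon genes were highest in wild type F3 at 2.195, Msh3+/- F1 at 1.342, Q140 Msh3+/- F2 at 1.55 and Q140 Msh3-/- F3 at 1.529 within their groups. Microglia markers were highest in wild type F3 at 5.434. Cholinergic interneuron markers were highest in Q140 Msh3+/- M4 at 3.921 and in Q140 Msh3-/- F4 at 3.997. Cortical markers were highest in Msh3+/- F5 at 3.827, with 2.692 the next in its group. Choroid plexus markers were highest in Q140 Msh3+/- F1 at 4.729, with 0.948 the next.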

How the results depend on the processing

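The fits without the choroid plexus library Q140 Msh3+/- F1 and the cortical library Msh3+/- F5 and the list tests without a library that stands apart in the list were chosen after seeing the data; the other alternatives were planned. Of 4027 values of 293 named-gene results under alternatives, 3578 kept direction and side of the threshold, 431 lost the call, 7 gained it and 11 reversed; of 649 values of 46 list results (lists past camera with a member called), 622 kept both and 27 lost the call by the direction that camera gives. The median itself turned sign in 6 of the 27: heat shock genes in Q140 against wild type (0.006 in the 3 FPKM fits) and choroid plexus markers in Q140 Msh3+/- against Q140 (-0.018) and Msh3+/- (-0.03) without those 2 libraries, and against Q140 without Q140 Msh3+/- F1 alone. Of the 5 of these values without a library that stands apart, activity-regulated genes (-0.36 without Q140 M2) and microglia markers (-0.087 without wild type F3) in Q140 against wild type kept the call, and activity-regulated genes in the interaction with Msh3-/- (0.307 without Q140 M2) and choroid plexus markers in Q140 Msh3+/- against Q140 (-0.016) and against Msh3+/- (0.015 without Q140 Msh3+/- F1) lost it. Of 13 further values, of lists past camera with no member called, 7 kept the call and 6 lost it, among them microglia markers (adjusted p = 0.0604) and interferon genes (adjusted p = 0.731) in Msh3+/- against wild type without wild type F3. Choroid plexus markers in the interaction with Msh3+/- kept it, at 0.68 against 3.26, without Q140 Msh3+/- F1. Interferon genes in Q140 against wild type, not past camera, went from -0.09 to 0.25 without wild type F3. All 11 reversals came without Q140 Msh3+/- F1, which holds the choroid plexus reads, and Msh3+/- F5: in Q140 Msh3+/- against Q140, Mfrp -0.17, Slc4a5 -0.40, Tmem72 -0.091 and Prlr -0.039; in Q140 Msh3+/- against Msh3+/-, Ttr -0.58, Slc4a5 -0.58, Mfrp -0.53, Tmem72 -0.063, Sostdc1 -0.03, Prlr -0.055 and Kl -0.015. RLE scaling, the stricter filter and the random block by code stem moved no count of genes by over 1.5 times.

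On log2 FPKM with offsets of 0.1 and 1, where libraries are scaled by their totals, the counts were 6030 and 6074 for Q140 against wild type, 795 and 831 for Q140 Msh3+/- against Q140, 4280 and 4343 for Q140 Msh3-/- against Q140, 2188 and 2177 for Q140 Msh3+/- against Msh3+/-, 1 and 1 for the interaction with Msh3+/-, and 1145 and 1190 for that with Msh3-/-; Msh3+/- against wild type gave 1 with an offset of 1 and 1 without a filter, and the sex difference 1 without a filter. With DESeq2 the counts were 649 for Q140 Msh3+/- against Q140, 25 for Q140 Msh3-/- against Q140 Msh3+/-, 29 for Q140 Msh3-/- against Msh3-/-, 19 for the interaction with Msh3+/- and 763 for that with Msh3-/-. Without a count filter they were 211, 9 and 280 for Q140 Msh3+/- against Q140, Q140 Msh3-/- against Msh3-/- and the interaction with Msh3-/-; more genes are then tested. With only the groups compared they were 1 for Msh3+/- against wild type, 4 for Q140 Msh3+/- against Q140, 23 for Q140 Msh3-/- against Msh3-/- and 1 for the sex difference, with fewer libraries behind the spread. Without the sex covariate Q140 Msh3-/- against Msh3-/- gave 9. Plate column as a covariate gave 1, 125 and 8 for Msh3+/- against wild type, Q140 Msh3+/- against Q140 and Q140 Msh3-/- against Msh3-/-. Plate row gave 1 for Msh3+/- against wild type, 553 for Q140 Msh3+/- against Msh3+/-, 2 for Q140 Msh3-/- against Msh3-/- and 64 for the interaction with Msh3-/-; in that interaction the mean size of the called genes went from 0.43 to 0.40 and the standard error set by the design grew 1.16-fold, and in Q140 Msh3-/- against Msh3-/- the size went from 0.53 to 0.56 with 1.26-fold, in Q140 Msh3+/- against Msh3+/- from 0.35 to 0.32 with 1.1-fold, and in Msh3+/- against wild type it was 0.94 in both with 1.13-fold. Without the 2 libraries Q140 Msh3+/- against Q140 gave 116. For the rest the cause was not tested.

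The shares kept were 23.9% on Msh3-/- and 50.7% on Msh3+/- with genes chosen and measured in the same libraries, whose chance values enter the choice, and 27.0% and 59.9% for the Pan-MSN list. With the Q140 libraries divided, 514 and 968 genes changed back in Q140 Msh3-/-, and 4 with 1 division in Q140 Msh3+/-. Called genes within 5 Mb of Htt made up 1.11% (Fisher exact p = 0.00767).

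Leaving out each library in turn gave 3242 to 4468 genes for Q140 against wild type, 5 to 7 for Msh3-/- against wild type, 1664 to 2936 for Q140 Msh3-/- against Q140, 980 to 1366 for Q140 Msh3+/- against Msh3+/- and 0 to 0 for the sex difference. It gave 1 to 3 for Msh3+/- against wild type (1 without Msh3+/- F4 or M3 or wild type F1, M1 or M4), 3 to 6 for Q140 Msh3-/- against Q140 Msh3+/- (6 without Q140 Msh3-/- F3) and 0 to 24 for the interaction with Msh3+/- (24 without Q140 M4). For Q140 Msh3-/- against Msh3-/- it gave 5 to 17 (9 and 7 without Q140 Msh3-/- F1 and F3, 8, 5 and 7 without Msh3-/- F2, M2 and M4). For the interaction with Msh3-/- it gave 262 to 935 (262, 276 and 935 without Q140 F1, M1 and M4, 286 without Q140 Msh3-/- F2, 302 without wild type M4). For Q140 Msh3+/- against Q140 it gave 73 to 992 (73, 113, 691, 259, 91 and 992 without Q140 F1, F2, F3, F4, M1 and M4, and 123, 755, 256 and 104 without Q140 Msh3+/- F1, F4, M1 and M4).

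With the replicate number as a block (replicate block) the counts were 3749, 2, 6, 343, 2371, 3, 1006, 15, 0, 475 and 0 in the order of the comparisons, Q140 against wild type to the sex difference. The numbers did not pair the libraries: 18 of 115 same-number pairs had a correlation of deviations over 0.1 (mean -0.00521), and 15 of 48 libraries were closest to their own number. Weak changes were often missed in the simulated data, which had 200 changed genes. There the interaction with Msh3-/- recovered 8% of genes that Q140 changed 1.3-fold, 30% at 1.5-fold and 72% at 2-fold. In that simulation 50% of the Q140 change was kept on Msh3-/-, so the interaction term itself was smaller than these folds. The real data had 3969 genes called in Q140 against wild type and kept 34.1% on Msh3-/-, so recovery there may differ.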

Other observations

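All families and tests in this part were chosen after the values were seen.

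Genes of 4 signalling families, few of them in the fixed lists, fell more often than they rose in Q140 against wild type. Of 12 measured genes with a Camk symbol, which are calcium/calmodulin kinases and the kinase inhibitors Camk2n1 and Camk2n2, 7 fell and none rose, such as Camk4 (-0.42), Camk2n1 (-0.40), Camkk1 (-0.34) and Camk2b (-0.30). Of 9 protein kinase C genes (Prkc) 6 fell and none rose, of 18 regulators of G protein signalling (Rgs) 9 fell and 2 rose, and of 24 calcium channel genes (Cacn) 10 fell, 1 rose and 13 did not pass. The lists fixed in advance already held 3 of the Rgs genes, 1 Cacn and 1 Prkc gene. In Q140 Msh3-/- against Q140, 7 Camk, 6 Prkc, 8 Rgs and 9 Cacn genes rose and 1 of each family fell. The families were picked for their values, so no test of them is given.

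Among 340 zinc finger genes (Zfp) 53 rose and 21 fell in Q140, and 8 rose and 24 fell in Q140 Msh3-/- against Q140. Of 14 small nucleolar RNA host genes (Snhg) 5 rose in Q140 and none fell. The medians of these 6 families in Q140 against wild type kept their sign under RLE scaling and on FPKM, but on FPKM that of Cacn went from -0.11 (-0.105) to -0.03 (-0.028), that of Prkc from -0.22 to -0.14 and that of Zfp from 0.04 to 0.12.

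Gm2420, a pseudogene on GRCm38 chromosome 5 at 32720330 to 32736194, 2.03 Mb from Htt, was at 0 to 0.136 CPM in the 24 libraries without Q140 and at 0.546 to 1.06 CPM in 20 of the 24 with Q140. In the other 4, Q140 Msh3+/- M2 and Q140 Msh3-/- F1, F3 and F4, it was at 0 to 0.0616 CPM. A hypothesis is that it marks DNA of another strain linked to the Q140 allele, lost by recombination in these 4. Among the 100 genes whose level follows Gm2420 most closely in the Q140 Msh3 mutant libraries, 3 lie within 5 Mb of it (Abhd1, Dpysl5 and Atraid), 3% against 0.794% of the genes tested (Fisher exact p = 0.0455), which is consistent with that hypothesis by a narrow margin. In the 4 libraries and in the other 20 with Q140, Abhd1 was at 3.57 to 4.04 and 5.73 to 8.62 CPM, Dpysl5 at 44.1 to 48.6 and 54.2 to 65.3 CPM, and Atraid at 36.8 to 39.9 and 28.8 to 34 CPM. These 3 were picked for following Gm2420, so the gap among the Q140 Msh3 mutants is partly built in. The Q140 group, not used to pick them, was at 5.73 to 8.2, 54.2 to 61.7 and 29.4 to 34 CPM, against 3.18 to 4.66, 37.5 to 54.3 and 34.5 to 42.5 CPM in the 24 libraries without Q140. A wrong Q140 label in these 4 libraries is argued against: by a score of the 3897 called genes beyond 20 Mb of Htt, 0 of them lay in the range of the libraries without Q140 (-1.12 to -0.998), their own range being -0.972 to -0.867. Of the 24 libraries with Q140, 1 lay in that range, Q140 Msh3-/- F2 at -1.03, and it had Gm2420 reads.

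Whether libraries with less Htt had a stronger Q140 effect was tested by the correlation of the Htt level with the Pan-MSN level in each Q140 group, a family of 3. In Q140 (n = 8) Pearson's r was 0.71 (exact permutation p = 0.0549, adjusted p = 0.165) and Spearman's rho 0.571 (exact permutation p = 0.151), and r was 0.94 without the 2 libraries farthest from the median Htt level. In Q140 Msh3+/- (n = 8) r was 0.0687 (exact permutation p = 0.884) and rho 0.143 (exact p = 0.752), with r at 0.0206 without 2 libraries. In Q140 Msh3-/- (n = 8) r was 0.295 (exact permutation p = 0.521) and rho 0.0476 (exact p = 0.935), turning to -0.134 without 2 libraries. None passed, and with 8 libraries a group a relation cannot be told apart from its absence.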
